A study of Mus musculus with 6 samples.

How the data were processed

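RNA from the livers of 6 mice aged 6 weeks was measured by sequencing, with 3 libraries of the genotype LiK and 3 of the genotype LiKM. Per the labels' protocols, the libraries were made with a stranded kit that selects messenger RNA. Reads were counted per gene with featureCounts and checked with FastQC 0.11.7, per the submitters' processing notes. The aligner, the genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of raw read counts, whole numbers that were not normalised, with 1 row per gene symbol and 1 column per mouse. Each column name matched the animal code in the title of a single sample, and 0 columns were left unused. The titles number the mice 1 to 3 within each genotype and give each mouse its own code, so the libraries were treated as separate animals.

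The counts were used as deposited. Of the 26608 gene symbols, 6335 had no count in any library. Genes were kept with the default expression filter of edgeR 4.0.16, a count of about 10 in at least as many libraries as the smaller group holds and a total count of at least 15, which left 13537 genes. Library sizes were scaled by TMM, with factors between 0.903 and 1.11. The genotypes were compared with the quasi-likelihood test of edgeR in R 4.3.3, with the genotype as the only term and no block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Standard errors of log2 fold changes were derived from the fitted coefficient and its F statistic. Levels are given as CPM, counts scaled to a common library size, after TMM scaling, as mean ± SD over the 3 mice of a genotype. The common biological coefficient of variation was 22.3%.

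Before the data were examined, 36 gene lists were fixed for liver functions, cell types, signalling pathways and checks of the tissue. Of 911 list memberships, 890 (97.7%) matched a symbol in the table, 21 of them through an older symbol looked up in the synonyms of the RefSeq table for GRCm38.p6. The 13 mitochondrially encoded genes, the immunoglobulin constant genes, Trac, Trbc2, Hbb-bt and Ahsp had no matching row and were not analysed here. The 33 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over those lists. The list for X inactivation and Y-linked genes (4 tested members) and the list of pancreas acinar markers (3 tested members) were too small for that test. Each list was also given a count of genes adjusted over the list alone.

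The genes to be named were also fixed by rule. They were a few genes fixed in advance, among them Mdm2 and Trp53, the 12 called genes with the largest rise and the 12 with the largest fall among genes with an average log2 CPM of at least 2, up to 4 called members of each list with the smallest adjusted p or, in a list with none, up to 2 members with the highest average level, and the Y-linked genes. Unnamed gene models were passed over. This gave 111 genes, of which 87 were called, and some of them are not reported here. Genes named outside this rule were chosen after their values were seen: Cdkn1a, Ccng1, Fas, Bbc3, Gdf15, Sesn1, Mki67, Ccnb1, Afp, H19, Col1a1, Acta2, Cd3e, Gzmb, Cd4, Zap70, Krt19, Sox9, Epcam, Hsd3b5, Serpina1e, Cyp2b13, Dusp6, Spry4, Myc, Clec4f, Stab2, Alb, Vegfa, Slc40a1, Sult1e1, Cyp17a1, Abcc4, Abcb4, Ddr1, Tubb4b and every gene named only in the closing section.

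Simulated counts with known answers were used to test the scripts at the real library sizes, on 13374 genes with 200 of them changed. The edgeR test recovered 51 of 100 genes changed 2-fold and 98 of 100 genes changed 4-fold, with 10 false calls among 13174 unchanged genes. A shifted list was called, and 0 unshifted lists were called. Each gene was simulated independently, so the simulated lists held no correlation between genes. The list result therefore does not show how camera behaves on the real lists, whose estimated correlation reached 0.615 (mitosis genes). The changed genes had been drawn from those with a mean count over 50. At 3 mice per genotype, changes of about 2-fold were found in about 51% of these simulated cases, and scarcer genes were not tried. Alternatives covered other scalings (DESeq2's median ratio, upper quartile, library totals, TMM without the 50 most abundant genes), the Wald test of DESeq2 1.42.0, limma-voom with sample weights, robust shrinkage, no filter, a stricter filter of at least 1 CPM in 3 libraries, a test against a 1.5-fold change, the replicate number as a block, and leaving out each library in turn. List tests were repeated with a correlation estimated for each list and with fry. A covariate for the Y-linked genes was planned only for libraries that differed by over 3 log2 units and was not needed.

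Gene-level counts sum reads over all exons of a gene, so they cannot show whether part of a gene has been removed. Closely related genes, such as the Mup, Gstm, Cyp2b, Cyp3a, H2, Gbp and tubulin families, share sequence, and how the counting treated reads that fit several members is not given in the sources used here, so values of single members of these families are uncertain. With the strand setting not known, reads from overlapping genes on opposite strands cannot be assigned with certainty. No genome coordinates are given because the build behind the deposited counts is not known.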

Results

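Liver RNA from 6 mice was sequenced, 3 of the genotype LiK and 3 of the genotype LiKM, all aged 6 weeks. The labels do not spell the genotype names out. As known from the published study and not from the labels, hepatocytes of LiKM mice differ from those of LiK mice in that they lack Mdm2, the ubiquitin ligase that holds the tumour suppressor p53 at a low level. The comparison thus asks what loss of Mdm2 in hepatocytes adds to the LiK liver. The libraries held 23007280, 20778717 and 24874343 counts in LiK and 20762712, 19909993 and 19981932 in LiKM, over 16847 to 17472 detected genes. The 50 most abundant genes took 35.8% ± 0.673 of the counts in LiK and 35.2% ± 1.71 in LiKM (SD, n = 3 each). Within a genotype, every pair of libraries differed by more than sampling noise, with a chi-square per gene between 34.6 and 119. On that measure LiK 3 lay nearer to LiKM 1 (68.7) and LiKM 2 (78.2) than to LiK 1 (119) or LiK 2 (98.9). Pearson correlation of log2 CPM instead placed LiK 3 nearer LiK 1 (0.9755) and LiK 2 (0.9776) than any LiKM library (0.9536 to 0.9631). The first principal component of log2 CPM held 53% of the variance and separated the genotypes, and the next held 18.2% and set LiKM 3 (−37.8) apart from LiKM 1 and LiKM 2 (28.4 and 20.2).

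Mdm2 itself was higher in every LiKM library. Its level was 28.8 ± 0.221 CPM in LiK and 102 ± 36.2 CPM in LiKM (n = 3 each), a log2 fold change of 1.83 (SE 0.27), with an adjusted p of 0.0196 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mdm2 is a transcriptional target of p53, and its gene-level count sums all exons, so the rise neither shows nor excludes a deletion within the gene. Trp53, which encodes p53, lay at 21.9 ± 2.92 CPM in LiK and 25.5 ± 6.79 CPM in LiKM, with a log2 fold change of 0.22 (SE 0.20) that was not called by edgeR (Benjamini-Hochberg adjusted p = 0.575). The Mdm2 call did not pass the threshold without LiK 1, LiK 2, LiK 3 or LiKM 2, with edgeR adjusted p of 0.084, 0.0778, 0.052 and 0.0708, while its log2 fold change stayed between 1.64 and 2.08 over the 6 omissions. With all libraries, Mdm2 also missed the threshold in edgeR's test against a 1.5-fold change (Benjamini-Hochberg adjusted p = 0.0511).

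**Figure D1:**
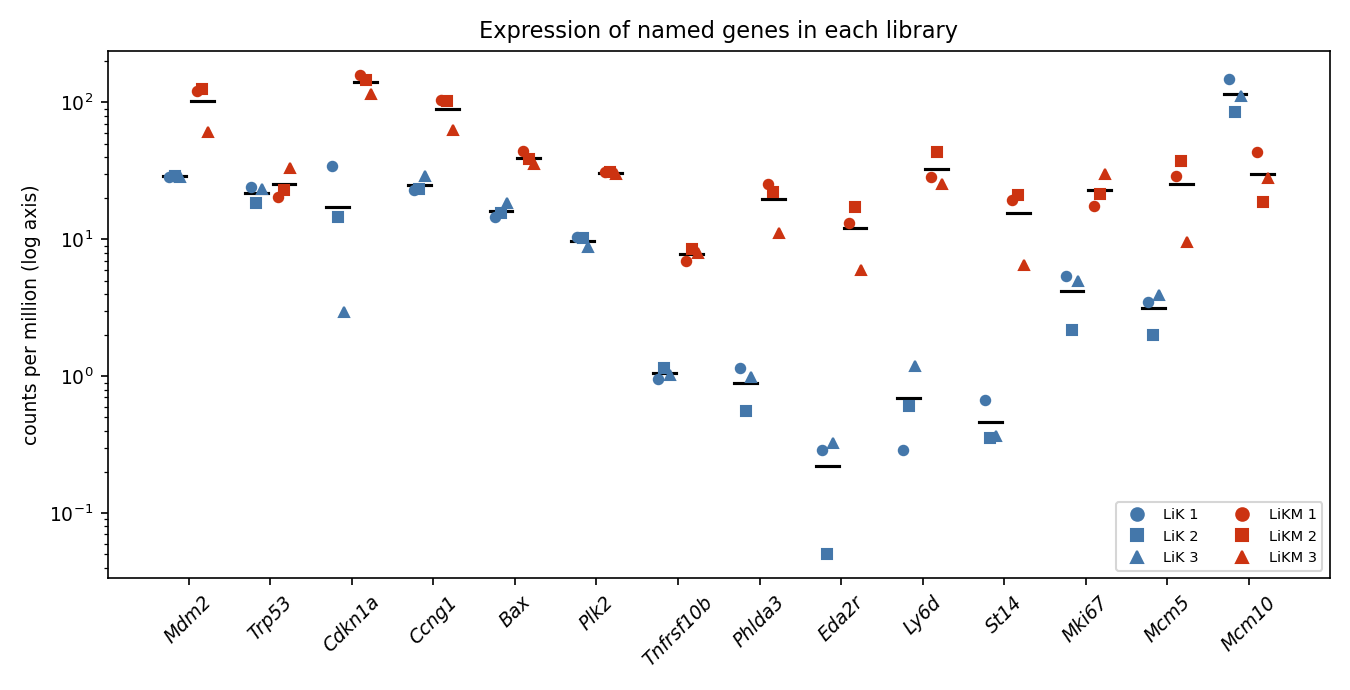
CPM after TMM scaling (log axis) of 14 genes in each of the 6 libraries, with LiK in blue, LiKM in red, marker shapes for the mouse number and a black bar at each group mean. Mdm2 rose from a mean of 28.8 to 102 CPM and Phlda3 from 0.898 to 19.6 CPM, Mcm10 fell from 115 to 30.2 CPM, and Cdkn1a spread from 2.96 to 34.4 CPM among the LiK libraries.

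The livers differed mainly by genes that were higher in LiKM. Of 13537 genes tested, 692 were higher and 110 lower in LiKM at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, so 86.3% of the 802 called genes were higher. The called genes included 549 that rose and 45 that fell by at least 2-fold. Among called genes with an average log2 CPM of at least 2, the largest rises were those of Psrc1, Eda2r, Ly6d, Ddit4l, St14, Ccl5, Phlda3, Cpt1c, Gstm3, Uhrf1, Pmm1 and Gtse1, with log2 fold changes from 7.81 down to 3.26. Among the 12 largest falls of called genes at that level, with log2 fold changes from −6.91 to −2.80, all but Cyp7b1 and Serpina12 were genes of the major urinary protein family. Psrc1 had 2, 0 and 2 counts in the LiK libraries and 389, 420 and 163 in LiKM, so its fitted fold change depends on the prior count. In each of the 802 called genes the 3 LiKM libraries lay on one side of the 3 LiK libraries, as did 29.6% of all genes tested, where chance gives 10%.

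The number of calls rested on single libraries. It was 31 without LiK 1, 19 without LiK 2, 311 without LiK 3, 376 without LiKM 1, 47 without LiKM 2 and 626 without LiKM 3, each with 2 mice left in that genotype. The 17 genes called in every one of these fits were Ccl5, Cd74, Ddit4l, Ddr1, H2-Aa, H2-Ab1, H2-Eb1, Lif, Ly6d, Mup17, Phlda3, Plk2, Polk, Psrc1, Tnfrsf10b, Top2a and Tubb4b, and of these Mup17 alone was lower in LiKM. All 802 called genes kept their direction in each of the 6 fits. Their libraries did not overlap between the genotypes, so this was all but fixed in advance and is no separate support.

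Many genes that p53 is known to switch on rose in LiKM, though not all. Of 40 tested p53 target genes, 22 rose, 0 fell and 18 did not pass edgeR's test, and 31 rose when p was adjusted over the list alone. Plk2, a kinase of the stress response, rose from 9.80 ± 0.922 to 30.7 ± 0.762 CPM (log2 fold change 1.65, SE 0.12). The death receptor gene Tnfrsf10b rose by 2.88 (SE 0.20), the DNA polymerase gene Polk by 1.66 (SE 0.13), the cyclin gene Ccng1 by 1.85 (SE 0.21) and Phlda3, which restrains AKT, by 4.43 (SE 0.40) on the log2 scale. The cell cycle inhibitor gene Cdkn1a had a mean of 17.3 CPM in LiK and 140 CPM in LiKM, but not a steady LiK level. The LiK libraries spread over 34.4, 14.6 and 2.96 CPM. Its log2 fold change of 3.02 (SE 0.73) was not called by edgeR (Benjamini-Hochberg adjusted p = 0.0591). Among the fits without a library, Cdkn1a was called only without LiK 3 (edgeR adjusted p = 0.0412). Other members that were not called were Fas (0.75), Bbc3 (0.78), Gdf15 (1.76) and Sesn1 (−0.01). The list's median log2 fold change was 1.31, with a camera Benjamini-Hochberg adjusted p of 2.13e-17, and adjusted p = 0.17 with an estimated correlation. The mean log2 CPM of the list lay 1.74, 1.78 and 1.27 above the LiK mean in LiKM 1, LiKM 2 and LiKM 3. Without LiK 1, LiK 2 or LiKM 2, the number of members called higher was 5, 5 and 7. It was 17, 16 and 24 without LiK 3, LiKM 1 and LiKM 3.

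Many cell division genes rose as well, in counts of bulk tissue that do not show which cell types held the transcripts. Of 30 mitosis genes, 21 rose and 29 rose when adjusted over the list alone, and all 30 had a positive log2 fold change. Top2a, the topoisomerase of dividing cells, rose from 2.55 ± 0.935 to 16.5 ± 2.09 CPM (log2 fold change 2.69, SE 0.28). The kinase gene Cdk1 rose by 2.19, the spindle gene Tpx2 by 2.33, Racgap1 by 2.31, Ccnb1 by 2.45 and the proliferation marker Mki67 by 2.45 on the log2 scale. Of 30 DNA replication and G1/S genes, 12 rose, 1 fell and 17 did not pass edgeR's test, against 21 higher and 1 lower when adjusted over the list alone. Gins2 and Mcm5, parts of the replicative helicase, rose by 3.11 (SE 0.47) and 3.01 (SE 0.52). Mcm10 went the other way and fell from 115 ± 31.7 to 30.2 ± 12.5 CPM, a log2 fold change of −1.93 (SE 0.33) with an edgeR Benjamini-Hochberg adjusted p of 0.0251. The medians were 2.18 for mitosis, with a camera adjusted p of 1.07e-18 and adjusted p = 0.201 with an estimated correlation, and 1.39 for replication, with a camera adjusted p of 2.23e-08 and adjusted p = 0.269 with an estimated correlation. LiKM 3 had the highest mitosis mean (2.39 above the LiK mean) and the lowest replication mean (0.59) of the LiKM libraries. Leaving out LiK 1, LiK 2, LiK 3, LiKM 1, LiKM 2 or LiKM 3 gave 3, 1, 9, 13, 1 and 14 called mitosis genes and 0, 0, 1, 1, 0 and 19 called higher replication genes, and the call of Mcm10 was kept only without LiKM 1. Mcm10 was also not called in the test against a 1.5-fold change.

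**Figure D2:**
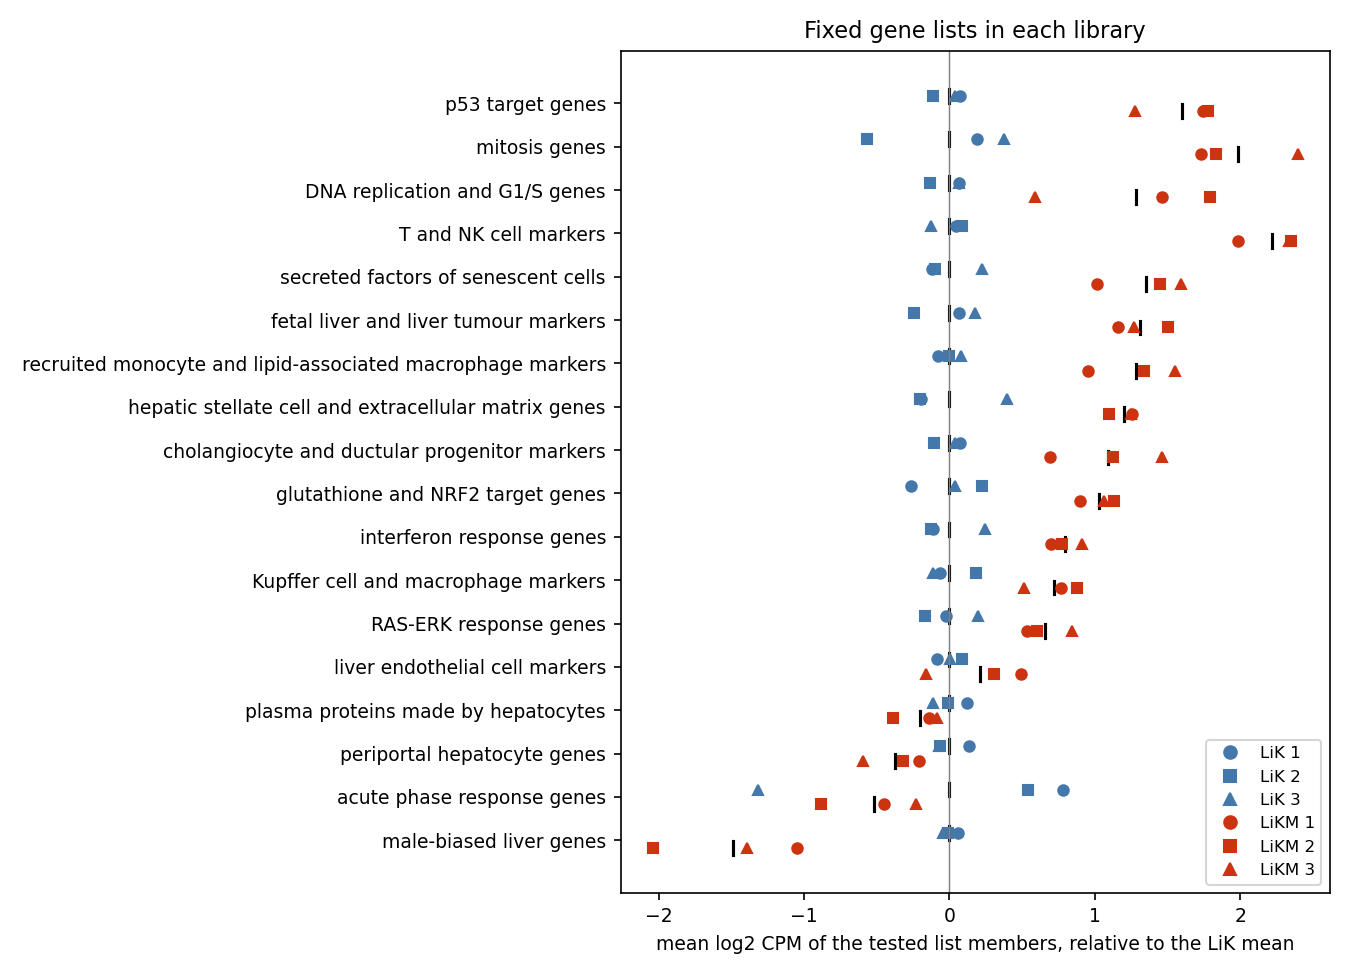
Mean log2 CPM of the tested members of 18 gene lists in each library, relative to the mean of the LiK libraries, with LiK in blue, LiKM in red, marker shapes for the mouse number and black bars at the group means. The p53 target list lies between 1.27 and 1.78 in LiKM and between −0.11 and 0.07 in LiK, the male-biased list lies between −2.04 and −1.05 in LiKM, and the acute phase list spreads from −1.32 to 0.78 within LiK.

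Some genes of factors that senescent cells are known to secrete rose in LiKM. Of 27 tested members, 13 rose and 0 fell, and 17 were higher and 1 (Vegfa, −0.43) lower when adjusted over the list alone. The chemokine gene Ccl5 rose from 0.328 ± 0.0726 to 8.70 ± 2.53 CPM (log2 fold change 4.72, SE 0.35), but it is also a member of the T and natural killer cell list. Lif, a cytokine of the interleukin 6 family, rose by 4.61 (SE 0.43), Icam1, an adhesion molecule, by 1.64 (SE 0.23) and the chemokine gene Cxcl10, also in the interferon list, by 2.33 (SE 0.36). The median was 1.23, with a camera adjusted p of 6.15e-08, and adjusted p = 0.201 with an estimated correlation. Of the tested members, 10 also belong to other lists, and without them 8 of 17 rose, a count chosen after the data were seen. Without LiK 1, LiK 2, LiK 3, LiKM 1, LiKM 2 or LiKM 3, the members called higher numbered 2, 2, 6, 8, 2 and 8.

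Markers of T and natural killer cells had the largest median change of the lists tested. Of 17 tested members, 13 rose and 0 fell, and 14 rose when adjusted over the list alone. Cd8a, the co-receptor of cytotoxic T cells, rose from 0.142 ± 0.0558 to 2.48 ± 0.35 CPM (log2 fold change 4.10, SE 0.37). The kinase gene Lck rose by 3.02 (SE 0.40), the cytokine receptor gene Il2rb by 2.31 (SE 0.29), the T cell receptor component Cd3e by 3.26 (SE 0.71) and the granzyme gene Gzmb by 2.12 (SE 0.40). Cd4 (−0.94) and Zap70 (0.12) were not called. These transcripts were scarce, with 2 to 4 Cd8a counts in each LiK library and 45 to 62 in each LiKM library. Members this scarce in LiK passed the expression filter only through their LiKM counts. The filter thus favours members that rose, which can raise the list median. Of 23 members with a row, 17 were tested. The list median was 3.02, with a camera adjusted p of 4.09e-13, and adjusted p = 0.17 with an estimated correlation. The list had 2, 1, 7 and 2 members called higher without LiK 1, LiK 2, LiK 3 or LiKM 2. With the filter of at least 1 CPM in 3 libraries, 6 members were called higher.

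Some macrophage and monocyte markers rose as well. Of 24 Kupffer cell and macrophage markers, 11 rose and 0 fell, and 19 were higher and 1 (Slc40a1, −0.44) lower when adjusted over the list alone. Tyrobp, a signalling adaptor of myeloid cells, rose from 9.21 ± 0.314 to 17.5 ± 1.71 CPM (log2 fold change 0.93, SE 0.13), and the protease gene Ctss rose by 1.19 (SE 0.16), while Clec4f, a marker of resident Kupffer cells, was not called (0.48, SE 0.15). Of 22 markers of recruited monocytes and lipid-associated macrophages, 11 rose and 17 rose when adjusted over the list alone, among them Capg (1.74, SE 0.29), Lgals3 (1.46, SE 0.20) and Lyz2 (0.63, SE 0.10). The medians were 0.81, with a camera adjusted p of 1.89e-08 and adjusted p = 0.255 with an estimated correlation, and 1.17, with a camera adjusted p of 9.95e-10 and adjusted p = 0.175 with an estimated correlation. Without LiK 1, LiK 2, LiK 3, LiKM 1 or LiKM 2, the called members numbered 0, 1, 3, 4 and 0 for the former list and 0, 0, 3, 6 and 0 for the latter, and both lists had 0 in the test against a 1.5-fold change.

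Some genes of hepatic stellate cells and extracellular matrix rose in LiKM. Of 33 tested members, 13 rose, and 32 rose when adjusted over the list alone, with all 33 log2 fold changes positive. The collagen genes Col6a3 and Col5a2 rose by 1.39 (SE 0.22) and 1.40 (SE 0.23), and Col1a1 rose from a mean of 16.9 to 50.2 CPM (log2 fold change 1.57, SE 0.30). Eln, which encodes elastin, rose by 2.35 (SE 0.40), and Lum, a matrix proteoglycan gene, by 1.63 (SE 0.30). Acta2, a marker of activated stellate cells, was not called (2.86, SE 1.08). The median was 1.02, with a camera adjusted p of 5.33e-14, and adjusted p = 0.201 with an estimated correlation. Without LiK 1, LiK 2, LiKM 1, LiKM 2 or LiKM 3, the members called higher numbered 0, 0, 1, 0 and 8. Without LiK 3, 18 members were called higher, and 0 were in the test against a 1.5-fold change.

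Some interferon response genes were higher in LiKM, as were 4 genes of major histocompatibility complex class II. Of 32 interferon response genes, 9 rose and 16 rose when adjusted over the list alone. The peptide transporter gene Tap1, also in the p53 target list, rose from 32.2 ± 3.28 to 62.3 ± 8.77 CPM (log2 fold change 0.95, SE 0.14). The GTPase gene Igtp rose by 1.46 (SE 0.23) on the log2 scale. The median was 0.74, with a camera adjusted p of 1.4e-08, and adjusted p = 0.201 with an estimated correlation. Of 12 tested B and plasma cell markers, 4 rose, with the same number when adjusted over the list alone. These 4 were Cd74, H2-Aa, H2-Ab1 and H2-Eb1, which encode class II molecules and their invariant chain and are also expressed by macrophages and dendritic cells. Their log2 fold changes lay between 1.95 and 2.27, and H2-Eb1 had an edgeR Benjamini-Hochberg adjusted p of 0.00482. The B cell list had a median of 0.84, with a camera adjusted p of 1e-05, and adjusted p = 0.259 with an estimated correlation. Without LiK 1, LiK 2, LiK 3, LiKM 1 or LiKM 2, the interferon list had 0, 0, 5, 4 and 0 members called higher, and it had 0 in the test against a 1.5-fold change.

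**Figure D3:**
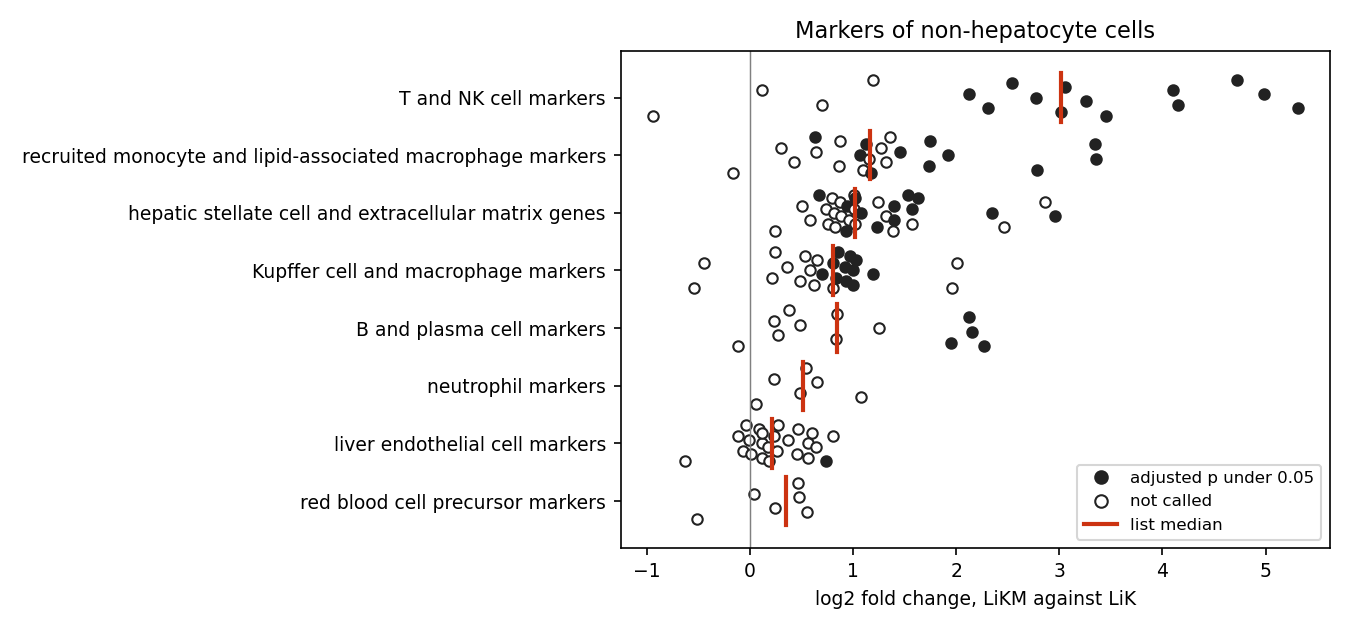
Log2 fold change (LiKM against LiK) of each tested marker in 8 lists of non-hepatocyte cells, with filled points for genes called at an adjusted p under 0.05, open points for the others and red bars at list medians; height within a list has no meaning. The T and natural killer cell list has a median of 3.02, the stellate cell and matrix list 1.02 and the endothelial list 0.21.

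Markers of other cell types held few calls. Of 24 liver endothelial markers, 1 rose, Plvap, which forms the diaphragms of fenestrae (log2 fold change 0.74, SE 0.10), and the count adjusted over the list alone was also 1. The scavenger receptor gene Stab2 was not called (0.19, SE 0.12), the list median was 0.21, and the camera adjusted p was 0.0757 (adjusted p = 0.613 with an estimated correlation). None of the 6 tested neutrophil markers was called by edgeR over all genes or adjusted over the list alone, with Csf3r at 0.65 and Prtn3 at 0.23, a list median of 0.52, a mean shift of 0.55 (SE 0.50) and a camera adjusted p of 0.288 (adjusted p = 0.588 with an estimated correlation). None of the 6 tested red cell precursor markers was called either way, with Alas2 at 0.04 and Slc25a37 at 0.24, a list median of 0.35 and a camera adjusted p of 0.296 (adjusted p = 0.613 with an estimated correlation). Of 5 adipocyte markers, Car3, a carbonic anhydrase gene that hepatocytes express as well, fell by 0.99 on the log2 scale, also when adjusted over the list alone, and the list had a median of −0.27 and a camera adjusted p of 0.0527 (adjusted p = 0.255 with an estimated correlation). The 3 tested pancreas acinar markers were not called over all genes or adjusted over the list alone, with Cela1 at −0.55 and Cela2a at 0.06, and their median of 0.06 and mean shift of −0.14 differ in sign. The call of Car3 was lost in each of the 6 fits without a library, and the endothelial list had 0 called members without LiK 1, LiK 2 or LiKM 2 and 2 without LiKM 3.

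Some male-biased liver genes were lower in LiKM, and a few female-biased genes were higher. Of 20 tested male-biased genes, 6 fell and 15 fell when adjusted over the list alone, and all 20 log2 fold changes were negative. Cyp7b1, an oxysterol hydroxylase gene, fell from 346 ± 141 to 44.0 ± 33.8 CPM (log2 fold change −2.97, SE 0.59), the cytochrome gene Cyp2d9 from 1856 ± 70.6 to 1000.1 ± 183 CPM (−0.89, SE 0.16) and Susd4 from 12.6 ± 2.39 to 2.33 ± 1.73 CPM (−2.43, SE 0.46). The steroid dehydrogenase gene Hsd3b5 (−1.63, SE 0.37) and Serpina1e (−1.27, SE 0.29) also fell. Major urinary protein genes took 2.90% ± 0.30 of all counts in LiK and 1.11% ± 0.179 in LiKM (SD, n = 3 each), with Mup7 at 8877 ± 2380 and 888 ± 648 CPM, but reads shared between the copies leave the value of each copy uncertain. Without the Mup genes, a subset chosen after the data were seen, 5 of 15 male-biased genes fell. Of 16 tested female-biased genes, 3 rose and 4 rose when adjusted over the list alone, namely Cyp3a44 (5.08, SE 0.81), Hao2 (3.67, SE 0.73), Cyp2b9 (2.65, SE 0.59) and, in the latter count only, Cyp2b13 (5.11, SE 1.23). The other female-biased genes were not called, and 6 of the 16 had negative log2 fold changes, such as Sult1e1 (−1.71, SE 1.27) and Cyp17a1 (−1.12, SE 0.47). The female-biased list had a median of 0.63 and a camera adjusted p of 0.0146, with adjusted p = 0.327 with an estimated correlation, and the male-biased list a median of −0.92 and a camera adjusted p of 2.46e-11, with adjusted p = 0.175 with an estimated correlation. The male-biased list had 0 called members without LiK 1, LiK 2 or LiKM 2, and 4 without LiK 3 or LiKM 3. Without LiKM 1 the list had 8. It had 0 in the test against a 1.5-fold change and 15 with DESeq2, and Cyp7b1 and Cyp2b9 were also not called with robust shrinkage. The female-biased list had 0, 0, 1 and 1 called members without LiK 1, LiK 2, LiKM 1 or LiKM 2, and 2 without LiKM 3.

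All mice carried Y-linked transcripts at similar levels. Ddx3y was at 55.7 ± 4.65 CPM in LiK and 55.5 ± 0.885 CPM in LiKM, and the log2 fold changes of the 4 tested Y-linked genes lay between −0.21 and −0.01, with 0 called by edgeR over all genes or adjusted over the list alone. Their median of −0.10 turned to 0.07 when library totals were the only scaling. Xist, which silences the X chromosome in females, had at most 5 counts in any library.

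**Figure D4:**
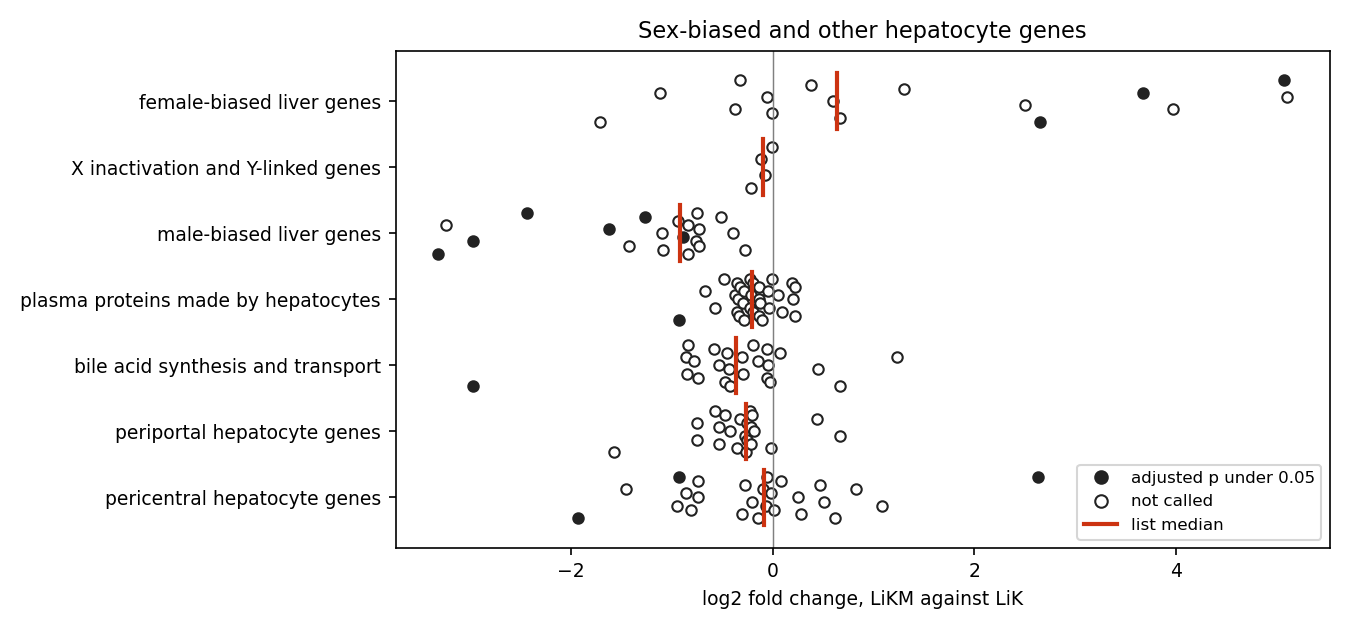
Log2 fold change (LiKM against LiK) of each tested member of 7 lists of sex-biased, sex-linked and other hepatocyte genes, with filled points for genes called at an adjusted p under 0.05, open points for the others and red bars at list medians; height within a list has no meaning, and only Y-linked genes of the X inactivation and Y-linked list were tested. The male-biased list has a median of −0.92, the female-biased list 0.63 and the plasma protein list −0.20.

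Few of the main secretory and zonal genes of hepatocytes were called. Of 32 plasma protein genes, 1 fell, Serpina1c (−0.93, SE 0.21), with 0 when adjusted over the list alone, a median of −0.20 and a camera adjusted p of 0.000333 (adjusted p = 0.305 with an estimated correlation). Alb, which encodes albumin, had a log2 fold change of 0.10. None of 22 periportal genes was called by edgeR over all genes or adjusted over the list alone, with Cps1, the first enzyme of the urea cycle, at −0.26 (SE 0.20), and the list had a median of −0.27 and a camera adjusted p of 0.000424 (adjusted p = 0.23 with an estimated correlation). Of 26 pericentral genes, the amino acid transporter gene Slc1a4 rose (2.63, SE 0.38) and Cyp2c37 (−0.93, SE 0.20) and the cation transporter gene Slc22a3 (−1.93, SE 0.33) fell, against 1 higher and 6 lower when adjusted over the list alone, with a camera adjusted p of 0.125 (adjusted p = 0.548 with an estimated correlation). The pericentral median was −0.08 and turned to 0.07 when library totals were the only scaling. These calls were lost without LiK 1, LiK 2 or LiKM 2, where the plasma protein and pericentral lists had 0 called members. Serpina1c was also not called without LiKM 1 or LiKM 3, with the replicate block or in the test against a 1.5-fold change. Without LiK 3 or LiKM 3, 1 pericentral gene was called lower, and 3 were without LiKM 1.

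Bile acid and lipid genes held few calls. Of 24 genes of bile acid synthesis and transport, Cyp7b1 fell, and 2 (Abcc4, 1.23, and Abcb4, 0.45) were higher and 6 lower when adjusted over the list alone, with a median of −0.36 and a camera adjusted p of 0.00222 (adjusted p = 0.208 with an estimated correlation). None of 24 cholesterol synthesis genes was called over all genes or adjusted over the list alone, with Sc5d at 0.19, while the list median was 0.44 with a camera adjusted p of 0.00467 (adjusted p = 0.538 with an estimated correlation). None of 30 genes of fatty acid oxidation and ketone body synthesis was called either way, with a camera adjusted p of 0.165 (adjusted p = 0.671 with an estimated correlation). The median of that list was −0.13, its mean shift was 0.24, and the median turned to 0.02 when library totals were the only scaling. None of 26 genes of fatty acid and triglyceride synthesis was called either way, with the lipogenic desaturase gene Scd1 at −0.09 (SE 0.66), Thrsp at −0.89 (SE 0.66), a list median of −0.18 and a camera adjusted p of 0.0702 (adjusted p = 0.487 with an estimated correlation). The bile acid list had 0 called members lower without LiK 1, LiK 2, LiKM 2 or LiKM 3, and 0 with robust shrinkage.

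Some glutathione and NRF2 target genes rose, whereas few genes of drug metabolism were called. Of 24 NRF2 targets, 9 rose and 17 rose when adjusted over the list alone. Gstm3, a glutathione transferase gene, rose from 20.5 ± 10.4 to 251 ± 41.3 CPM (log2 fold change 3.62, SE 0.38), Gstm2 by 1.71 (SE 0.20), the sulfiredoxin gene Srxn1 by 1.51 (SE 0.18) and the quinone reductase gene Nqo1 by 1.19 (SE 0.19). The median was 0.80, with a camera adjusted p of 1.14e-08, and adjusted p = 0.201 with an estimated correlation. Of 31 drug metabolising genes, Cyp2c37 and Ugt3a1 (−0.99, SE 0.21) fell, with 2 lower when adjusted over the list alone, a median of −0.20 and a camera adjusted p of 0.00108 (adjusted p = 0.256 with an estimated correlation). The NRF2 list had 2, 0, 4, 5 and 1 members called higher without LiK 1, LiK 2, LiK 3, LiKM 1 or LiKM 2, and the drug list had 0, 0, 1, 1, 0 and 0 called members without LiK 1, LiK 2, LiK 3, LiKM 1, LiKM 2 or LiKM 3.

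Markers of fetal liver, liver tumours and biliary cells rose in part. Of 21 fetal liver and liver tumour markers, 9 rose and 12 rose when adjusted over the list alone. Ly6d, a surface protein gene, rose from 0.694 ± 0.457 to 32.5 ± 9.79 CPM (log2 fold change 5.50, SE 0.44). The imprinted noncoding RNA genes Rian and Meg3 rose by 2.18 (SE 0.23) and 1.68 (SE 0.19). The gene Pkm, held under its older symbol Pkm2, rose by 0.96 (SE 0.13), and its count does not tell its isoforms apart. The fetal serum protein gene Afp rose by 2.45 (SE 0.38), while H19 was not called (2.47, SE 1.07). Of 23 cholangiocyte and ductular progenitor markers, 4 rose and 14 rose when adjusted over the list alone. These 4 were the membrane protease gene St14 (5.05, SE 0.56), Prom1 (2.57, SE 0.44), Cd24a (1.53, SE 0.32) and Lgals3, which macrophages express as well. The biliary genes Krt19 (1.61, SE 0.46), Epcam (1.56, SE 0.43) and Sox9 (1.12, SE 0.48) were not called. The fetal list had a median of 1.37 and a camera adjusted p of 1.51e-06, with adjusted p = 0.17 with an estimated correlation, and the biliary list a median of 1.09 and a camera adjusted p of 3.44e-06, with adjusted p = 0.226 with an estimated correlation. Without LiK 1, LiK 2, LiK 3 or LiKM 2, the fetal list had 1, 1, 5 and 3 members called higher. The biliary list had 0, 0, 2 and 1 in the same order. Without LiKM 1 or LiKM 3, the fetal list had 8 and 7 and the biliary list 5 and 3. Without the members that other lists hold, a subset chosen after the data were seen, 2 of 19 biliary markers rose.

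Targets of RAS and YAP signalling held single calls. Of 23 RAS-ERK response genes, the cyclin gene Ccnd1 rose from 30.5 ± 17.6 to 127 ± 48.6 CPM (log2 fold change 2.06, SE 0.44), and Dusp6 was the other of 2 that passed when adjusted over the list alone. The feedback inhibitor genes Dusp6 (0.54, SE 0.13) and Spry4 (−0.56, SE 0.29) and the oncogene Myc (0.82, SE 0.77) were not called over all genes. The median was 0.60 and the camera adjusted p 0.00148, with adjusted p = 0.183 with an estimated correlation. Of 22 YAP and TAZ targets, the receptor tyrosine kinase gene Axl rose by 0.88 (SE 0.14), also when adjusted over the list alone, with a median of 0.41 and a camera adjusted p of 0.00316 (adjusted p = 0.256 with an estimated correlation). Both calls were lost without LiK 1, LiK 2, LiKM 1 or LiKM 2, and that of Axl also without LiK 3. Ccnd1 was also not called with robust shrinkage or with the replicate block, and neither gene was called in the test against a 1.5-fold change.

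Some cell death genes rose, and a stress response gene, Atf3, rose as well. Of 28 cell death and inflammasome genes, 6 rose and 11 rose when adjusted over the list alone. Bax, a pore-forming death gene, rose from 16.1 ± 2.03 to 39.6 ± 4.69 CPM (log2 fold change 1.29, SE 0.14), the apoptosome gene Apaf1 by 1.56 (SE 0.17) and Pmaip1 by 2.49 (SE 0.44), all also p53 targets. The median was 0.60, with a camera adjusted p of 5.7e-06, and adjusted p = 0.17 with an estimated correlation. Of 29 genes of the integrated stress and unfolded protein responses, the transcription factor gene Atf3 rose by 1.90 (SE 0.28), also when adjusted over the list alone, and the list had a median of 0.16 and a camera adjusted p of 0.157 (adjusted p = 0.548 with an estimated correlation). The cell death list had 1 called member without LiK 1, LiK 2 or LiKM 2, where Atf3 was not called, and the stress list had 2 called members without LiKM 3.

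Acute phase genes varied within LiK. None of 28 members was called by edgeR over all genes or adjusted over the list alone, with Hp at 8783 ± 5001 CPM in LiK and 4563 ± 1039 CPM in LiKM and Hpx at a log2 fold change of −0.75 (SE 0.42), and the list had a median of −0.45 and a camera adjusted p of 0.0519 (adjusted p = 0.613 with an estimated correlation). None of 36 cytosolic ribosomal protein genes was called either way, with Rpl10 at −0.22 and Rps2 at −0.16. The ribosomal list had a median of −0.15 and a camera adjusted p of 0.000118 (adjusted p = 0.327 with an estimated correlation), and the median turned to 0.02 when library totals were the only scaling, which moved the median of all genes from −0.00 to 0.16.

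Over the fixed lists as a whole, camera called 24 of 33, with 18 higher and 6 lower in LiKM, at its preset correlation of 0.01. With a correlation estimated for each list it called 0, with 7 lists at an unadjusted p under 0.05, and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, called 20. In the test against a 1.5-fold change, 13 p53 targets, 6 mitosis genes, 6 T and natural killer cell markers, 4 B and plasma cell markers, 3 members each of the fetal, NRF2 and cell death lists, 2 secreted factors and 1 member each of the biliary, replication, female-biased and pericentral lists were called higher, and no other list member was called.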

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

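The 4 list subsets were chosen after the data were seen, and all other alternatives before. The main counts were 692 genes higher and 110 lower in LiKM and 24 lists. Scaling by library totals gave 1039 higher and 63 lower and moved the median log2 fold change of all genes to 0.16, with 94.3% of calls higher against 86.3%. DESeq2 called 1180 higher and 365 lower, limma-voom with sample weights 1063 and 260, and the test against a 1.5-fold change 115 and 12. Leaving out a library gave 18 to 525 genes higher and 1 to 101 lower, with 2 mice left in a genotype. The cause of these shifts was not tested. Median-ratio and upper-quartile scaling, TMM without the 50 most abundant genes, robust shrinkage and both filters gave 754 to 852 calls. A correlation estimated for each list left 0 lists called, and the other settings with list tests gave 20 to 27. All 802 called genes kept their direction in every setting where they were tested. This was largely fixed in advance, since the libraries of these genes did not overlap between the genotypes. Over 17 settings, the 111 named genes gave 1886 comparisons with the main result, of which 1573 had the same call, 311 lost it, 2 gained it and 0 called genes changed direction; outside the leave-one-out fits, 52 lost it. Of these, Ccnd1, Cyp2b9, Cyp7b1 and Mup12 lost it with robust shrinkage, Ccnd1 and Serpina1c with the replicate block, and the rest in the test against a 1.5-fold change. Of 87 called named genes, 18, 16, 63, 68, 23 and 75 were still called without LiK 1, LiK 2, LiK 3, LiKM 1, LiKM 2 and LiKM 3. The p53 list without Psrc1 and Gtse1 held 20 called members of 38.

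The mice share numbers across genotypes, but same-numbered deviations correlated by 0.267, −0.000281 and 0.127, and the codes name separate animals, so the numbers were not used as pairs. The replicate block gave 669 genes higher and 166 lower, 605 of them shared with the 802, and 25 lists. Not every library correlated best with its own number. The Y-linked covariate was not run, and DESeq2 and the test against 1.5-fold gave no list calls. Depth limits scarce markers, such as Cd8a with 2 to 4 counts per LiK library.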

Other observations

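The gene families and the tests of explanations in this part were chosen after the results were seen. Many genes of antigen presentation and many interferon-induced GTPase genes rose in LiKM. Of 9 tested genes of major histocompatibility complex class II, its invariant chain and its transcriptional activator Ciita, 7 rose, with a median log2 fold change of 1.87 (camera adjusted p over 10 families 1.47e-10, and adjusted p = 0.0816 with an estimated correlation). Of 11 guanylate-binding proteins, which act against intracellular pathogens, 7 rose, with all 11 log2 fold changes positive and a median of 1.54 (camera adjusted p 9.45e-08, and adjusted p = 0.0816 with an estimated correlation). Of 7 immunity-related and T cell GTPases, 5 rose, among them Tgtp1 by 2.91. Of 7 class mu glutathione transferases, 3 rose, with a median of 0.81, and 0 of 11 growth hormone axis genes were called, with a median of −0.22 and a camera adjusted p of 0.0202 (adjusted p = 0.186 with an estimated correlation). With an estimated correlation, the adjusted p of the 10 families lay between 0.0816 and 0.186. The checkpoint genes Pdcd1 and Cd274 were called by edgeR, with 0, 0 and 2 Pdcd1 counts in LiK and 21, 18 and 34 in LiKM and a log2 fold change of 1.81 for Cd274, while Lag3 (0.44) and Tox (−0.37) were not. Gzmk, a granzyme gene of T cells, had 0 counts in the LiK libraries and 10, 22 and 14 in LiKM, at least about 15.6-fold higher against a floor of 3 counts over the LiK group. Sprr1a, an epithelial stress gene, had 0 counts in LiK and 38, 139 and 162 in LiKM, at least about 115-fold higher on the same basis.

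Of 9 tubulin genes, whose copies share reads, 4 rose, with Tubb4b at a log2 fold change of 1.56 and all 9 positive. The receptor genes Notch1 (1.63) and Notch3 (0.99) rose among 11 Notch receptors and targets, of which Hes1 (0.30) and Sox9 (1.12) were not called. Of 18 major urinary protein genes, 11 fell and all 18 log2 fold changes were negative, with a median of −3.17. Ddr1, a collagen receptor gene, rose by 2.60 and stayed called whichever library was left out. Acute phase genes split the LiK mice. Saa1 had 91824 and 125026 counts in LiK 1 and LiK 2 and 1024 in LiK 3, against 5092, 1629 and 3198 in LiKM, and Lcn2 was at 1451, 754.9 and 18.3 CPM against 291, 144 and 194 CPM.

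Of 20 male-biased liver genes, 6 fell in LiKM, while the mice were alike in Y-linked transcripts. Female mice among the LiKM libraries are argued against, since each held Ddx3y at 54.6 to 56.4 CPM and at most 5 Xist counts. The shift of summed Y-linked counts exceeded that of the male-biased list by 1.40 (SE 0.31) on the log2 scale. The Y-linked shift itself was −0.10 (SE 0.04), so that difference came mostly from the fall of the male-biased list. A smaller share of hepatocytes is argued against as the whole cause, since male-biased genes outside the Mup family lay 1.08 lower than plasma protein genes (difference −1.08, SE 0.20). The plasma protein list itself shifted by −0.21 (SE 0.12), so a smaller share as part of the cause stays open. The 5 called members outside the Mup family argue against reads shared between Mup copies as the whole cause. That count was known when the test was set and does not show how Mup reads were assigned. The male-biased list had 0 called members without LiK 1, LiK 2 or LiKM 2. Weaker growth hormone signalling, which maintains male-biased expression, may contribute and stays open, because the mean shift of 7 genes it induces was −0.73 with an SE of 0.46. The genotype as such, hormone levels and feeding stay open and were not tested.

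T and natural killer cell markers were higher in LiKM by 2.22 (SE 0.14) on the log2 scale as a list mean. Members scarce in LiK passed the expression filter through their LiKM counts, which can raise this mean and its differences from other lists. A loss of hepatocytes that raises every other cell type alike is argued against by the difference of 2.01 (SE 0.30) from endothelial markers. More blood in the tissue pieces is argued against as the whole cause by the difference of 1.65 (SE 0.30) from haemoglobin alpha transcripts. Lymph node tissue is argued against as the whole cause by the difference of 1.54 (SE 0.55) from 7 tested B cell genes. Haemoglobin alpha itself was higher in LiKM by 0.58 (SE 0.26) and the B cell genes by 0.68 (SE 0.48), so either may be a part of the rise. A candidate explanation is that more T or natural killer cells, or more active ones, were present in LiKM livers, and counts of bulk tissue leave these open. This is a hypothesis found and tested on the same libraries.

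Mcm10 fell in LiKM while 5 of the 8 other minichromosome maintenance genes tested rose, and its level in LiK, 115 CPM, was far above the 3.14 CPM of Mcm5. Its upstream neighbour on the same strand in the GRCm38.p6 annotation, Optn, also fell, with a log2 shift of −0.51 (SE 0.02). Transcripts reading through from Optn at an unchanged share are argued against as the whole cause, since Mcm10 lay 1.46 further down (difference −1.46, SE 0.41). A change in the share that reads through was not tested and stays open. A transcript other than the one used in dividing cells might be counted under this symbol, which counts per gene cannot show. The Mcm10 call was lost without LiK 1, LiK 2, LiK 3, LiKM 2 or LiKM 3 (edgeR adjusted p 0.0921, 0.0668, 0.0558, 0.0763 and 0.05) and in the test against a 1.5-fold change (edgeR adjusted p 0.0724).

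The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many genes were called (802, with 0 as the highest of the other splits). As many lists were called in 1 of the 10 splits (24, with 22 as the highest of the others). Every other split mixed the genotypes within each group, so a genotype difference widened the spread within groups and lowered the gene calls. The 0 gene calls of the other splits were thus nearly fixed in advance. These splits cannot show what chance would give, and no conclusion is drawn from them.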
